A study of Drosophila melanogaster with 2 samples.

How the data were processed

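Peak lists from a transcription factor ChIP-seq experiment on Drosophila melanogaster embryos were analysed, 2 biological replicates of 1 group. Per the labels, embryos were 0 to 16 hours old, chromatin was fragmented by sonication to 200 to 800 bp, and the assembly is dm6. Per the manifests deposited with the samples, each list derives from the replicate alignments and 1 common control alignment. The aligner, the peak caller and the threshold on irreproducible discovery rate (IDR) are not given in the sources used here. The authors deposited 30000 candidate regions for each replicate, 30000 for the pooled replicates, and a final list of 6091 peaks kept by IDR. The authors' signal value of each peak is used to describe and rank peaks within its own list, and it is not scaled between lists. The deposited −log10 q values reach a ceiling of 4.07, held by 97.0% of final peaks, and were not used for ranking. Replicates were called separately and also pooled, and the final list was made from both.

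Summits were placed on the Ensembl annotation (release 115), whose sequence names and lengths hold every region, and sequence was taken from the reference of the same assembly. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. A promoter summit lay within 500 bp of a TSS of any gene other than an annotated transposable element. Each summit was then given 1 class, in the order promoter, 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic. Non-final pooled candidates (23909) were the background of class tests, and genes with a pooled candidate summit at a TSS were that of gene list tests. RNA gene lists were set against the protein-coding background. Lists matched by symbol can hold unrelated genes: HisCl1 is among the 6 counted histone genes.

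Shares were compared by Fisher's exact test, arms by the exact binomial test, and sequence words by the exact McNemar test between the window reaching 50 bp to each side of the summit and a window of the same width 500 bp away on a side drawn at random. Adjusted p-values are Benjamini-Hochberg values over all arms, classes, lists, motifs or 6-mers, with a threshold of 0.05. Intervals of shares are exact Clopper-Pearson 95% intervals and those of odds ratios are Woolf intervals, with a continuity correction where a cell is 0. They cover counting over peaks or genes, which are not independent replicates. No depth was available to weigh the replicates, and no test between groups could be made. The 43 gene lists and 20 motifs were fixed before the data were examined, and 39 lists had the 5 background genes needed for a test. The rank bins and the 6-mer followed in more detail were chosen after the data were seen.

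Named genes follow a rule fixed before the data were examined. It takes the 15 strongest peaks within 500 bp of a protein-coding TSS, the 3 members with the strongest promoter peak of each list past the threshold, and hng1, hng2, hng3 and Adf1. It also takes the 5 strongest peaks outside promoters. One gene that the rule takes is not reported here. Alternatives were a higher signal threshold, each replicate alone, other windows and summit distances, other backgrounds, nearest TSS only, 10000 rotations of bound labels, another flank and, added later, 20 shuffles that keep dinucleotide counts, peaks found in both replicates only, and arms with candidates only.

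The tests were tested on simulated data. For the gene list test, 4 of 6 changed lists were called and 0 of 34 unchanged ones. The simulated lists held more background genes than most lists tested here, so that rate does not carry over to small lists. For the 6-mer test, a word planted in 10% of windows ranked 1 of 2080, and random positions gave 0 calls. Those positions lacked the difference in G+C between real summits and flanks (34.2% against 43.7%), so the 0 calls do not cover its effect. Random draws of the candidates gave a promoter share p under 0.05 in 7 of 100 cases.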

Results

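Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos of 0 to 16 hours, males and females pooled. The embryos came from a transgenic line that carries CG9437 with green fluorescent protein (GFP) at its C terminus, an insertion that the labels tie to hng1. hng1 (hinge1) encodes a MADF-BESS domain protein, a family of DNA-binding proteins that includes Adf1. The 2 biological replicates form 1 group, so no comparison between conditions was possible, and the comparisons below are made within the genome. A free-text label calls each sample an input control, whereas the assay label, the antibody label and the output types of the files describe a transcription factor ChIP. The lists are described here as ChIP peak lists on that basis. Read numbers are not given in the sources used here, so the depth of each replicate is unknown.

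The final list held 6091 peaks, and the 3 strongest lay at the promoters of RN-tre, Pi3K21B and larp. These peaks fell in 5920 distinct regions, since some regions held more than 1 summit. Signal, the authors' value for each peak, ran from 148 to 19974 with a median of 258. The final list was identical to the 6091 pooled candidates of highest signal, out of 30000. The comparison of final with non-final candidates is therefore a comparison of strong with weak regions of 1 list. Peaks were spread over the arms at 44.1 to 47.8 per Mb, except on chromosome 4, where 33 peaks gave 24.5 per Mb. The share of chromosome 4 (0.542%) was below its share of the length (0.980%; exact binomial test, two-sided, adjusted p = 8.9e-04). Arms 2L (47.8 per Mb) and 3L (47.6 per Mb) both had an adjusted p of 0.0083 in the same test, which included chromosome Y. Y carried no candidate in any list, so its own adjusted p (4.1e-71) says nothing of binding there, and its length lowers the expected share of every other arm. With the 6 arms that hold candidates, an alternative chosen after the data were seen, 2L and 3L no longer passed (exact binomial test, adjusted p = 0.136 for both) and chromosome 4 did (6.6e-04). Among the 3045 peaks of higher signal, the exact test over 7 arms gave an adjusted p of 0.0626 for chromosome 4 and 0.409 for 3L. Without replicate 1, 2L did not pass (exact test over 7 arms, adjusted p = 0.0584).

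The final list was made from the replicates, so its recovery in them follows in large part from that selection. At final peaks, the pooled signal was close to the sum of the replicate signals (median ratio 0.998). RN-tre and Pi3K21B ranked first and second by signal in each replicate's own list, and larp ranked 3 and 5. Of the 6091 final peaks, 5884 (96.6%; exact Clopper-Pearson 95% interval 96.1 to 97.0) had a candidate summit within 100 bp in replicate 1. In replicate 2 the number was 5787 (95.01%; 94.4 to 95.5), and 5603 (92.0%; 91.3 to 92.7) had one in both. When each replicate's list was shortened to its 6091 strongest candidates, 4348 summits of replicate 1 (71.4%; 70.2 to 72.5) had a partner in replicate 2. Circular shifts of the replicate 2 summits gave 0.906% on average and at most 1.30% over 100 shifts. The signal values of the replicates at 5603 final peaks had a Spearman rho of 0.76, across peaks, which are not independent replicates. Summit distance sets these shares: at 50 bp the share found in both replicates was 68.2% and the share of strongest candidates with a partner was 52.7%.

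Final peaks lay at promoters more often than weaker candidates. Summits within 500 bp of an annotated transcription start site (TSS) numbered 3323 of 6091 (54.6%; 53.3 to 55.8), against 6259 of 23909 non-final candidates (26.2%). The odds ratio was 3.39 (95% interval 3.19 to 3.59; Fisher's exact test, two-sided, with a p too small for the software to represent). The same windows cover 13.3% of the chromosome arms. The share fell with rank, from 82.5% (76.5 to 87.5) of the 200 strongest peaks to 47.5% (45.3 to 49.7) of those ranked 4001 to 6091. Of 3180 summits near a protein-coding TSS, 76.2% lay upstream of it, with quartiles at -207 and -7 bp. Promoter peaks had a median signal of 283 against 236 for other final peaks, by a two-sided permutation test with p = 1e-05, the smallest that 100000 resamples can give. Introns held 30.8% of final summits against 43.9% of non-final ones (Fisher's exact test, adjusted p = 1.0e-77), and intergenic sequence 11.7% against 22.2% (adjusted p = 1.1e-81). Coding exons held 25 final summits (0.410%) against 731 non-final ones (3.06%; exact test, adjusted p = 1.2e-43). Untranslated regions and other exons were also lower. The call for other exons was lost among the 3045 peaks of higher signal (exact test, adjusted p = 0.0683) and without replicate 2 (0.0512). Classes exclude each other and promoters are taken first, so the higher promoter share by itself lowers the shares of the other classes. Among summits outside promoters, introns and other exons made up a larger part of final than of non-final summits. The lower shares of introns and other exons therefore do not show that strong peaks avoid them. Classes were not tested among summits outside promoters.

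**Figure D1:**
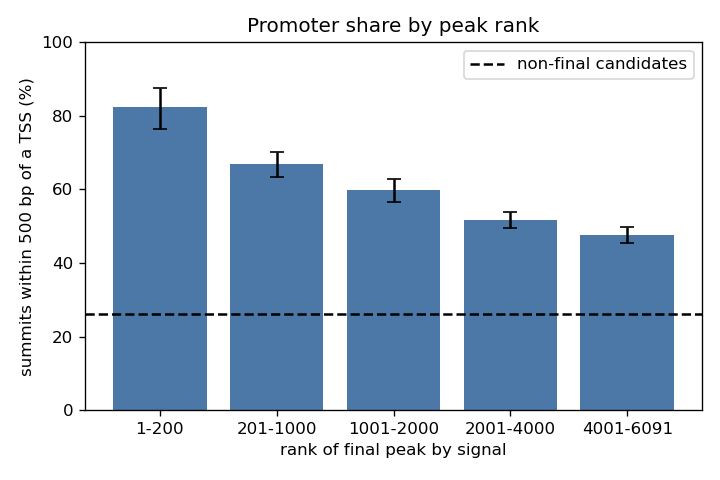
Percent of final summits within 500 bp of a TSS (y axis) by rank of the peak by signal (x axis). Bars are shares with exact 95% intervals, and the dashed line is the share among non-final candidates (26.2%). The share falls from 82.5% to 47.5%.

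Of the 15 strongest promoter peaks, 9 lay within 500 bp of TSSs of 2 or more protein-coding genes, and the names below are those of the nearest TSS. The summit at RN-tre, a Rab GTPase-activating protein gene, had the highest signal (19974) and lay on chromosome 2R at position 13990786 of dm6, at -79 bp from the TSS (negative values are upstream). The peak spans 13990163 to 13991454 and also lies within 500 bp of a TSS of mam, a gene of the Notch pathway. Pi3K21B, the regulatory subunit of phosphoinositide 3-kinase, followed with 19064 on 2L at 297722, at -158 bp. The RNA-binding protein gene larp had 18400 on 3R at 28335689, and the endocytic adaptor gene lap 17884 on 3R at 7186880. The chromatin remodeller gene kis (16949), the TATA-binding protein gene Tbp (16396) and the replication licensing gene dup (15857) had summits at -261, -49 and -66 bp. TBC1D23, qless, adp, btz, bon, Hrs and pcs completed the leading group with signals from 13391 to 18286. The peak of rank 16 (13360) lay 3 bp from a TSS shared by mRpL53 and CG33155. Outside promoters, the strongest peak (13476) was intergenic on 3R at 26137461, 313 bp from CG6142. It was followed by intergenic peaks near CG7985 (10228), bor (9922) and CG31689 (8584), and by a peak in an intron of the cadherin gene CadN (7737), on 2L at 17716050. The tagged gene itself had a promoter peak of modest height, 277 at rank 2739, with ranks of 2330 and 5217 in replicates 1 and 2. Its relative hng3 had 515 at rank 1150, and hng2 and Adf1 had candidate regions but no final summit at a TSS.

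Cytosolic ribosomal protein genes had a final promoter peak more often than other genes. Of 7055 protein-coding genes with a candidate summit at a TSS, 3511 (49.8%) had a final one. Of the cytosolic ribosomal protein genes, 69 of 85 (81.2%) did, with an odds ratio of 4.42 (2.56 to 7.63; Fisher's exact test, two-sided, adjusted p = 8.9e-08). With all protein-coding genes as background the odds ratio was 9.09. RpLP1 (1563) and RpS27 (1000.2) had the strongest peaks of this list, at ranks 213 and 405. Mitochondrial ribosomal protein genes did so in 43 of 56 cases (76.8%; odds ratio 3.37, 1.81 to 6.27, exact test, adjusted p = 5.3e-04), led by mRpL32 (17441), mRpL53 (13360) and mRpL43 (12077). The peaks of mRpL32 and mRpL53 were also those of qless and CG33155. When each summit counted only for its nearest TSS, 27 of 56 mitochondrial genes (48.2%) remained against 38.2% of other genes, an odds ratio of 1.51, and the call was lost (exact test, adjusted p = 0.418).

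Transfer RNA genes had final peaks less often than protein-coding background genes (49.8%), in 20 of 85 cases (23.5%; odds ratio 0.311, 0.188 to 0.514, Fisher's exact test, adjusted p = 2.0e-05). Of all pooled candidates, 6091 of 30000 were final. The lower shares of RNA genes in this paragraph are therefore relative to protein-coding promoters and do not show that strong peaks avoid RNA genes. The neighbouring tRNA:Ala-CGC-1-1, tRNA:Ala-CGC-1-2 and tRNA:Ala-CGC-1-3 had the strongest (1648, 1648 and 1365), and the first 2 share 1 summit. Their summits lay at 366, -394 and -477 bp from the TSS. The rotation of bound labels, which allows for neighbouring genes, was run on protein-coding lists only. The exact test counts neighbouring tRNA genes that share a summit as separate genes. Small nucleolar RNA genes, 10 of 41 (24.4%), were lower with an adjusted p of 0.014, a call lost with windows of 250 bp (0.234) and 1000 bp (0.520), without replicate 1 (0.0522) or replicate 2 (0.0811) and among the 3045 peaks of higher signal (0.516). The strongest peaks within 500 bp were those of snoRNA:U49:66Da (685), snoRNA:Psi28S-2949 (643) and snoRNA:Or-CD11a (620). Their summits lay at -490, -189 and -488 bp from the snoRNA TSS, and whether they belong to other genes was not tested. None of 9 cuticle protein genes had a final peak (exact test, adjusted p = 0.030). That call was lost in the permutation that rotates bound labels along the gene order (adjusted p = 0.0696), and in the exact test with windows of 250 bp (0.129) and 1000 bp (0.0620), nearest TSS only (0.153), the 3045 peaks of higher signal (0.254) and without replicate 1 (0.0905). The other 34 tested lists did not pass. Among them, by the exact test, segmentation genes had 2 of 13 (adjusted p = 0.109), small nuclear RNA genes 0 of 8 (0.0506), cytochrome P450 genes 6 of 25 (0.0807), insulator and architectural proteins 9 of 12 (0.340), translation factors 23 of 35 (0.275), oxidative phosphorylation 29 of 56 (0.994) and the MADF-BESS family 3 of 8 (0.994). Cytochrome P450 genes passed as lower with windows of 250 bp (3 of 18, exact test, adjusted p = 0.0356) and 1000 bp (7 of 33, 0.0136), and segmentation genes with 250 bp (1 of 11, 0.0412). Heat shock protein genes, 7 of 9 in the final list (exact test, adjusted p = 0.350), passed as higher without replicate 1, with 9 of 9 (0.0141). With all protein-coding genes as background, 4 more lists passed as higher in the exact test: the Polycomb group (12 of 19, adjusted p = 0.0018), insulator and architectural proteins (0.0074), translation factors (0.0206) and RNA polymerase II machinery (0.0482). Histones (3 of 118, 2.8e-10), odorant (3.8e-07), gustatory and ionotropic receptors (both 6.3e-06), cytochrome P450 (1.1e-04) and small nuclear RNA genes (5.3e-04) then passed as lower. In this background, genes without any candidate count as lacking a final peak. Only 6 of the 118 histone genes had a candidate summit at a TSS, and 3 of those 6 had a final one. Lists with under 5 genes in the background were counted only: immune response 4 of 4, ionotropic receptors 1 of 4, haemocytes 0 of 3 and odorant receptors 0 of 2.

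**Figure D2:**
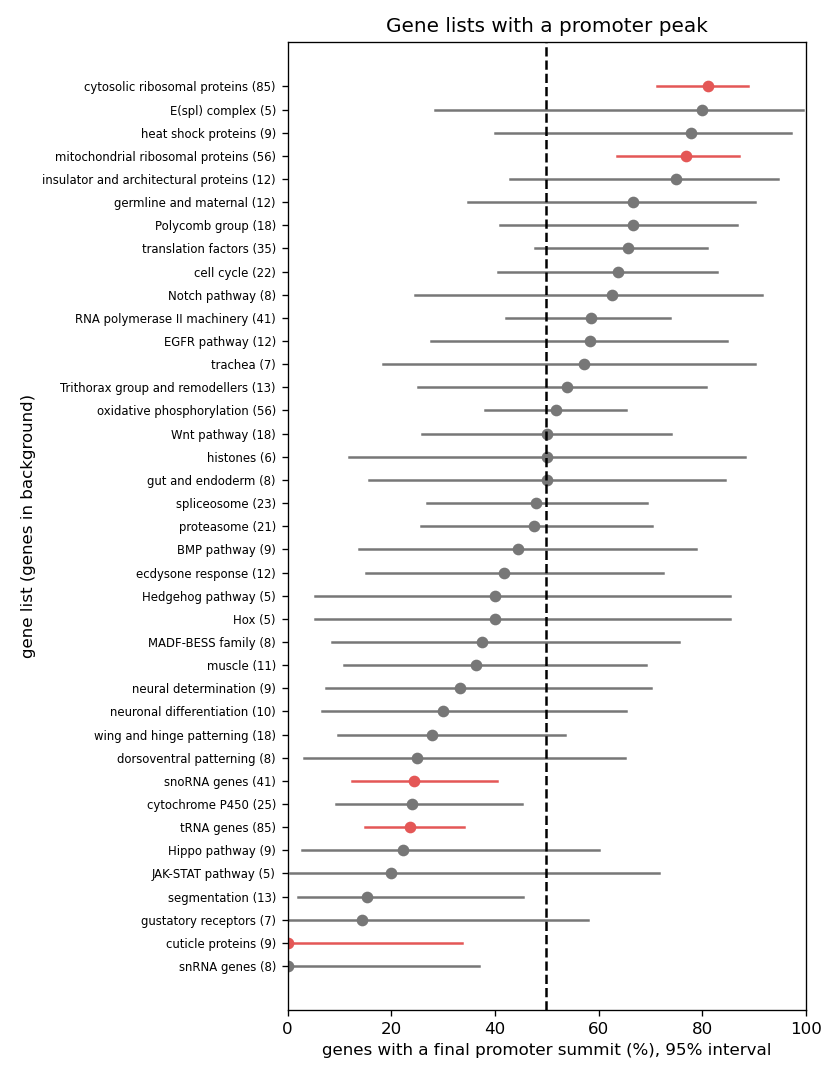
Percent of genes of each list with a final promoter summit (x axis), among list genes with a candidate summit at a TSS (number after each name). Points are shares with exact 95% intervals, the dashed line is all protein-coding background genes (49.8%), and the lists past the adjusted threshold are in red, with cytosolic ribosomal proteins at 81.2% and tRNA genes at 23.5%.

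The 6-mer ACGTAA had the highest ratio of summits to flanks among 6-mers at 100 or more summits, and it ranked 10 by p. It was present in 621 of 6091 windows reaching 50 bp to each side of the summit (10.2%) and in 128 windows centred 500 bp away (2.10%), a log2 ratio of 2.27 (exact McNemar test, two-sided, adjusted p = 1.4e-80). The share fell from 54.0% (46.8 to 61.1) of the 200 strongest peaks to 6.07% (5.09 to 7.18) of those ranked 4001 to 6091. In the flanks it lay between 1.5% and 2.38% in every rank bin. Overlapping words CGTAAC (1.77), TACGTA (1.68), AACGTA (1.64) and ACGTTA (1.51) followed by log2 ratio. Of 2080 6-mers, 511 were higher at summits and 1029 lower. The windows differed in composition: summits held 34.2% G+C and flanks 43.7%, and all 36 6-mers without G or C were higher. Against shuffles of the summit windows that keep dinucleotide counts, ACGTAA stayed higher (log2 ratio 0.97) but ranked 12, and ATCGAT, part of the Dref-type element, ranked first (1.66).

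**Figure D3:**
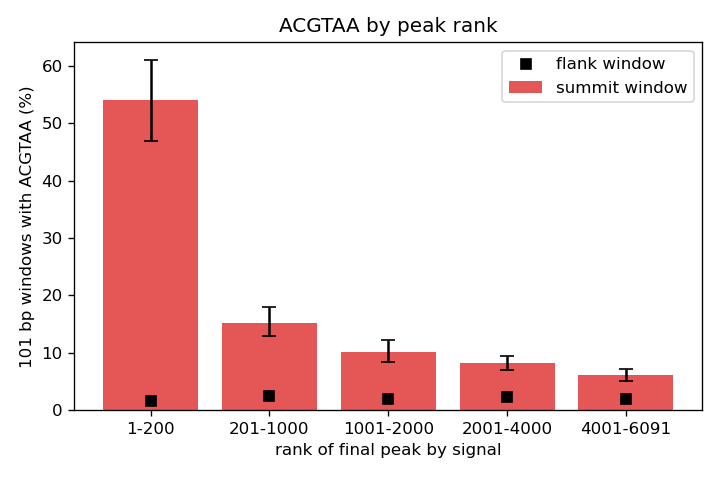
Percent of windows (50 bp on each side of the centre) with ACGTAA on either strand (y axis) by rank of the final peak by signal (x axis). Bars are summit windows with exact 95% intervals and squares are flank windows. Summit windows fall from 54.0% to 6.07%, and flank windows stay at or under 2.38%.

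Among 20 known motifs, 7 were more frequent at summits than in flanks and 6 less frequent. The DNA replication-related element TATCGATA, bound by Dref and BEAF-32, was in 2.04% of summit windows against 0.213% of flanks (exact McNemar test, adjusted p = 4.6e-23). The shorter CGATA was in 15.9% against 11.3%, Motif 1 in 0.936% against 0.197% and Ohler 7 in 5.42% against 3.46%. AT-rich words were also higher, with the TATA box in 23.8% against 11.8%, the homeodomain core in 10.4% against 5.53% and the GATA site in 21.9% against 15.9%. The GC-rich triplets known for Adf1 were lower at 1.10% against 3.78% (exact test, adjusted p = 5.1e-22), as were GAGA at 1.53% against 3.12%, the CT repeat at 0.640% against 1.90% and CACGTG at 0.755% against 1.61%. The Zelda motif (0.279% against 0.640%, adjusted p = 0.0076) and the initiator (8.55% against 9.82%, adjusted p = 0.026) were also lower in the exact test. Without replicate 1, the log2 ratio of the Dref-type element fell from 3.16 to 2.52 and that of the CT repeat moved from -1.55 to -0.675. With the flank 250 bp away, the log2 ratio fell from 3.16 to 1.13 for the Dref-type element and from 2.16 to 0.771 for Motif 1, and Ohler 7 (adjusted p = 0.0641) and the initiator (0.0911) did not pass the exact test. Between final and non-final promoter summits, the log2 odds ratio of the Dref-type element was 0.686 (exact test, adjusted p = 7.8e-04), and Motif 1 (0.0760) and CACGTG (0.0979) did not pass. Ohler 7 was higher at final promoter summits (odds ratio 1.48, 1.25 to 1.74). Outside promoters it was lower at final summits (2.20% against 2.94%, odds ratio 0.744, 0.569 to 0.973). The initiator was also lost without replicate 2 (exact test, adjusted p = 0.198) and among the 3045 peaks of higher signal (0.5002). Against shuffled summit windows, the GATA, homeodomain, GAGA, CT repeat, initiator and Adf1-type results went the opposite way, so their direction depends on the comparison. Between final and non-final promoter summits, these motifs all kept the direction found against flanks and passed the exact test. The odds ratios there were 1.23 for GATA, 1.56 for the homeodomain core, 0.531 for GAGA, 0.488 for the CT repeat, 0.724 for the initiator and 0.405 for Adf1-type triplets. Against the shuffles, the TATA box stayed higher by a small margin, at 23.8% against a shuffle mean of 21.0%, and the Zelda motif lay within the shuffle range (0.246% to 0.542%).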

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

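The shuffles, the restriction to peaks found in both replicates and the restriction to arms with candidates were chosen after the data were seen. Of the main values and counts, 46 were labelled unchanged and 17 moved. A count was unchanged within a fixed ratio of its main value, and a replicate share inside its main interval. The promoter share was unchanged if it kept its call. Counts could therefore differ and be unchanged, as with 3 arms against 4 without replicate 1. For single arms, classes, lists, motifs and ACGTAA, 220 stayed, 26 lost their call, 11 gained one and 21 went the opposite way. The shares found in each replicate moved in 6 of 6 cases, all with summit distance. The promoter share stayed past its threshold in every alternative run, from 41.8% with a window of 250 bp to 64.9% with 1000 bp. With a higher signal threshold, the list held 3045 peaks by construction, 2 arms passed instead of 4 and 1 list was lower instead of 3, with fewer peaks tested. Both arm counts include chromosome Y, which has no candidate. With the 6 arms that have candidates, 1 passed, chromosome 4, and X (45.4 per Mb) turned from above to below its share without passing either time. The share found in both replicates (92.0%) was 68.2% at 50 bp, 98.2% at 200 bp and 99.3% with any overlap. Partners among the strongest candidates (71.4%) were 52.7% at 50 bp, 79.0% at 200 bp, 81.4% with any overlap and 76.7% with lists of 3045. With all protein-coding genes as background, 6 lists were higher and 9 lower, against 2 and 3. With nearest TSS only, 1 was higher. Rotation left 0 lower among protein-coding lists, and leaving out 1 replicate left 1 to 2 lower. Against shuffles, 12 motifs were higher instead of 7. The log2 ratio turned to 1.80 for GAGA, 0.98 for Adf1-type triplets, 0.15 for the initiator and 2.11 for the CT repeat, and to -0.15 for GATA and -0.24 for the homeodomain core. Without passing in any setting, the odds ratio of oxidative phosphorylation (1.08) turned to 0.831 with the higher signal threshold and 0.846 with peaks found in both replicates. That of the MADF-BESS family (0.605) turned to 1.03 with 1000 bp, 1.79 with all protein-coding genes, 1.36 with the higher signal threshold and 1.07 without replicate 1, but was 0.610 without replicate 2. That of RNA polymerase II machinery (1.43) turned to 0.749 with nearest TSS only, where it did not pass. That of histones (1.01, 3 of 6 genes) turned to 0.659 with 250 bp, 0.769 with 1000 bp, 0.124 with nearest TSS only, 0.455 with the higher signal threshold, 0.565 with peaks found in both replicates and 0.533 without replicate 1, passing in none. It was 2.04 without replicate 2 and 0.0769 with all protein-coding genes (3 of 118), where it passed and most of the list had no candidate. The cause was not tested for the changes other than those by construction. Depth is unknown, so what it limits could not be computed.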

Other observations

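The tests of ACGTAA against shuffles, against non-final candidates and by rank were chosen after the 6-mer was seen. The tests of the ribosomal protein odds ratio and the hng1 locus were written before the main tests were run. Those of ACGTAA at ribosomal protein peaks, shared promoters and transposable elements were written after the 6-mer, the list tests and the strongest peaks had been seen, and before their own values were computed.

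Final promoter summits lay near TSSs of more than 1 gene more often than non-final ones did. Of 3180 final summits near a protein-coding TSS, 1246 (39.2%) lay within 500 bp of TSSs of 2 or more genes, against 1130 of 5616 non-final ones (20.1%). The odds ratio was 2.56 (2.32 to 2.82; Fisher's exact test, two-sided, p = 2.3e-81). Annotated transposable elements held 20 final summits (0.328%) against 207 non-final ones (0.866%), an odds ratio of 0.377 (0.238 to 0.597; exact test, p = 4.1e-06). That test did not separate promoter from other summits, whose shares differ between the lists (54.6% against 26.2% at promoters). How much of the difference follows from this was not tested. Peaks with ACGTAA most often had it as AACGTAAC (19.3% of them, followed by AACGTAAT with 13.7%), at 120 summits and 9 flanks (exact McNemar test, adjusted p = 1.0e-24 over 16 extensions). ACGTAA was chosen for its ratio in these same windows, so words that contain it start out higher at summits. That p-value therefore does not support the longer word over the 6-mer. In 379 final peaks the nearest copy lay within 25 bp of the summit, 15.2 peaks per bp, against 4.16 per bp at 200 to 250 bp. Among the 200 strongest peaks, 48 (24.0%) had 2 or more copies in the summit window, against 25 of 2091 (1.20%) in the weakest bin.

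The first pattern is ACGTAA at final summits. Dinucleotide composition of the summit windows alone is argued against, since the observed 10.2% exceeds the highest of 20 shuffles, 5.94%. The ratio to the shuffle mean (log2 0.97) is well below that to flanks (2.27). Flank windows were not shuffled, and 12 of 20 known motifs also exceeded their shuffles. GAGA did so although it was lower at summits than in flanks, so exceeding shuffles does not set ACGTAA apart. A word equally frequent at all promoter summits is argued against as well, since final promoter summits carried it more often than non-final ones (10.95% against 4.27%; odds ratio 2.76, 2.34 to 3.25), and final summits outside promoters did too (9.28% against 3.92%). The TATA box (odds ratios 1.67 at promoters and 1.79 outside), the homeodomain core (1.56 and 1.58) and the GATA site (1.23 and 1.27) were also higher in both comparisons. Strong and weak regions were compared, so this result does not set ACGTAA apart from AT-rich words in kind. The ACGTAA share of 54.0% in the strongest bin fits the hypothesis that ACGTAA, or a longer word around it, places the tagged protein. Longer words were tested only in the windows from which ACGTAA was chosen. Another protein bound at the same sites stays open, since no untagged line or input list was analysed here.

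The second pattern is the final peaks at promoters. Non-specific signal at highly transcribed genes was predicted to raise the ribosomal protein genes, and the lower bound of their odds ratio was 2.56, so that explanation stays open for them. None of 100 final peaks at cytosolic ribosomal protein promoters had ACGTAA (upper 95% limit 3.62%), against 345 of 3080 other promoter peaks (11.2%; odds ratio 0.0394, 0.00244 to 0.636, exact test, p = 2.1e-05). Their median rank was 2327.5, against 2670 for the other promoter peaks, and the strongest ranked 213. The word was also absent at 5 of the 15 strongest promoter peaks, RN-tre and Pi3K21B among them, so its absence does not mark ribosomal protein peaks alone. No biological explanation could be tested between conditions, since the design holds 1 group.

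The third pattern is the hng1 locus. Extra copies of the tagged hng1 locus in the transgenic line could raise candidates around it. There were 8 pooled candidate summits within 10 kb, between the median of 6 and the 95th percentile of 16 over 13968 protein-coding genes, so the count decides neither way.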
